A study of Mus musculus with 6 samples.

How the data were processed

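Total RNA of bone marrow-derived macrophages from C57BL/6 mice had been extracted with TRIzol and made into Illumina libraries, per the labels' protocols. The labels put 6 samples into 3 groups of 2: cells given PBS, cells given 5 µM KN93 and cells given 10 µM KN93. The values deposited by the authors are FPKM, fragments per kilobase of gene and per 1000000 fragments, in 1 table of 54446 entries with 4 decimals and a column for each sample. Each column name carries the prefix DXM, which no label explains, so what it marks is unknown. The unit comes from the name of the deposited table and from the values, and no further scaling between samples is stated. The reads had been aligned with HISAT2 to the mouse genome build GRCm38, per the submitters' processing notes. The version of HISAT2, the counting tool, the annotation, the use of strand and any filter are not given in the sources used here. Without a stated use of strand, fragments of overlapping and antisense genes cannot be told apart, and close paralogs may share fragments. Every value column of the table belonged to 1 of the 6 samples, and no sample was left out.

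Gene IDs were matched to GENCODE M21, an annotation of GRCm38, for 54409 entries (99.93%), which gave coordinates, biotypes and summed exon lengths. Symbols came from the deposited table, and 93 symbols were used by more than 1 entry. For nearly all low values of the matched entries, FPKM times exon length was a whole multiple of one step per sample, so the fragments behind the values of these entries could be recovered. Of the values of up to 20 fragments, 98.8% to 99% came out whole within 0.1 fragment. The step also gave the library total behind the FPKM of each sample. In units of 1000000 fragments, these totals ran from 24.2 to 28.4, while the recovered fragments summed to between 26.1 and 30.7, more than the implied totals. The totals therefore set the scale of the values and are not the number of fragments counted in genes. At these depths 1 fragment of a gene with 1000 exon bases is worth between 0.0352 and 0.0414 FPKM. The recovered fragments were used for depth, for the comparison of replicates with counting noise and for 1 alternative test.

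Genes with at least 1 FPKM in at least 2 of the 6 samples were tested, which left 12722. The FPKM values were not counts, so log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend), with the group as a factor of 3 levels and all 6 samples in one fit, so that the groups shared one estimate of the spread. The fit had 3 residual degrees of freedom, to which eBayes added 2.72. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. The 3 comparisons were 5 µM against PBS, 10 µM against PBS and 10 µM against 5 µM. The difference between the 2 dose steps was tested in the same fit. A pseudocount of 1 FPKM makes the fold change of low genes smaller than the ratio of their FPKM.

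Before the data were examined, 33 gene lists, the tests, the rule for named genes and the alternatives were fixed, except where the text says otherwise. The lists held 923 entries and 858 distinct genes, of which 764 entries were tested, and 29 lists had at least 5 tested genes. Some genes stood in more than 1 list, among them 13 of the 30 macrophage identity genes, 2 of the 9 neutrophil markers and 1 of the 19 stromal markers tested, and macrophages can express part of the markers of other cell types. Each list was tested against all other genes with camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 29 lists. An estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. The named genes were those called and without overlap between the groups, with a symbol that is not a predicted-gene name: for each dose against PBS the 8 with the largest rise and the 8 with the largest fall, and between the doses the 5 largest in each direction. For each list described, up to 4 tested members with the smallest unadjusted p in that comparison were added, as were Camk2a, Camk2b, Camk2d, Camk2g and Camk4 and the genes of a result in the closing section. In the 4 lists with fewer than 5 tested genes all tested members were named, a choice made after the data were seen. The text gives some of these list members with values and follows the others only in counts over the alternatives. Apart from these, a result that the rule would name is not reported here.

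The alternatives were a pseudocount of 0.1 FPKM, no filter except a value above 0 in 1 sample, a filter of 5 FPKM in 2 samples, median-of-ratios scaling (factors of 0.9781 to 1.0281), quantile normalization, no intensity trend, only the samples of the 2 groups compared, the replicate number as a block, a log2 fold change of at least 1 as well, and each sample left out in turn. A fit with voom in limma on the recovered fragments of 12717 genes with a matched length, and a correlation and overlap of the doses with each set against a different PBS sample, and the alternatives for the difference of the steps and for calls in both comparisons, were added after seeing the data. Each named gene was followed through the alternatives in each comparison that called it. Where a range of adjusted p over the alternatives is given, it leaves out the estimated correlation, whose p stands on its own. The test was checked on fragments simulated for 10 µM against PBS for 12432 genes of equal spread beyond counting noise, 50 changed by each of 4 folds. It called 40% of genes changed 1.25-fold, 72% changed 1.5-fold and 94% changed 2-fold or 4-fold in the right direction, and 14 of 12199 unchanged genes. Real spreads differ by gene, so these rates may not hold. In the same simulation a shifted list had a camera p of 1.41e-36 and an unshifted list 0.663. Chance values of comparisons that share the PBS samples came from 50 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and figures.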

Results

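Gene expression was measured by RNA sequencing in bone marrow-derived macrophages of C57BL/6 mice, cells grown from marrow and differentiated in culture. The cells had been treated with PBS, a buffer, or with KN93, a small-molecule inhibitor of the calcium/calmodulin-dependent protein kinases CaMKII and CaMKIV. KN93 was given at 5 µM or at 10 µM, and each of the 3 groups held 2 samples. The labels do not give the duration of treatment, and nothing says that the 2 samples of a group came from separate cultures or animals. The p-values below therefore measure only the spread between these samples, which may be technical. Expression values are FPKM, given as mean ± SD (n = 2 per group). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and where an error follows one it is the standard error from limma. The median of a gene list is the median log2 change of its tested members.

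Nearly all low FPKM values were whole multiples of the value of 1 fragment, which gave the depth of each sample. The implied library totals, in units of 1000000 fragments, were 26.9 and 28.3 with PBS, 26.3 and 27.7 at 5 µM, and 24.2 and 28.4 at 10 µM. Between 11964 and 12175 genes reached 1 FPKM in a sample, and 12722 genes were tested. Across genes, which are not independent replicates, the 2 samples of a group had Pearson correlations of 0.9895 with PBS, 0.9899 at 5 µM and 0.99 at 10 µM. Pairs from different groups ranged from 0.93 to 0.9776. Each pair of one group differed by more than counting noise. The median chi-square per gene was 1.08 with PBS, 1.24 at 5 µM and 1.61 at 10 µM, where counting noise gives 0.455. No pair was therefore treated as 1 library deposited again, which does not show that the cultures were separate. The first principal component held 71.1% of the variance. It placed the PBS samples at 36.5 and 35.3, the 5 µM samples at -4.4 and -4.24, and the 10 µM samples at -30.1 and -33.1.

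Of the kinases that KN93 inhibits, Camk2g and Camk2d were the only CaMKII or CaMKIV genes above the expression filter. Camk2g was 7.46 ± 0.14 FPKM with PBS, 5.63 ± 0.051 at 5 µM and 5.03 ± 0.339 at 10 µM. It fell at both doses, with log2 changes of -0.35 ± 0.06 and -0.49 ± 0.06 (limma adjusted p = 0.00949 and 0.00142). The call at 5 µM was lost without the PBS replicate 2 (adjusted p = 0.0569) and without the 5 µM replicate 2 (adjusted p = 0.055, range over the alternatives 0.00208 to 0.0569). Camk2d was 3.50 ± 0.0351, 3.76 ± 0.0395 and 3.97 ± 0.319 FPKM in the same order, and neither dose passed the test against PBS (limma adjusted p = 0.403 and 0.126). Camk2a, Camk2b and Camk4 stayed below the filter, with mean FPKM of 0.0655, 0.409 and 0.0752 with PBS. Camk2a had 13 and 14 recovered fragments in the PBS samples and 10 and 11 in the 10 µM samples, and Camk4 had 8 and 6 against 1 and 2. On GRCm38, Camk2g lies on chromosome 14 at 20734875 to 20794088 and Camk2d on chromosome 3 at 126596302 to 126846326. In the wider list of 17 tested CaMK and calmodulin genes, Camk1d fell from 14.3 ± 0.83 to 8.15 ± 0.327 and 4.81 ± 0.0312 FPKM. Camkk1, which encodes a kinase that activates CaMKI and CaMKIV, fell from 5.12 ± 0.723 to 2.02 ± 0.0515 and 0.915 ± 0.118 FPKM. Camkk2 rose at 10 µM, from 4.97 ± 0.289 to 8.18 ± 0.085 FPKM. At 10 µM 5 fell and 5 rose (5 and 6 adjusted over the list alone), and at 5 µM 4 fell and 2 rose (4 and 4 adjusted over the list alone). The list as a whole did not pass against the other genes in any comparison (camera adjusted p = 0.936 at 5 µM, 0.42 at 10 µM and 0.156 between the doses). Fry, which asks whether the genes move on balance one way, called it in each (adjusted p = 0.00472, 0.000389 and 0.00208), the lowest of the alternatives, which reached 0.994, 0.545 and 0.243. At 5 µM its median was 0.01 and its mean -0.04.

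The first comparison asked which transcripts differed between cells given 5 µM KN93 and cells given PBS. Lists of cell cycle, matrix, chemokine and macrophage activation genes were lower, and lists of lysosomal, antigen presentation, stress response and p53 target genes were higher. With an estimated correlation none of these lists passed (smallest camera adjusted p = 0.41). Cx3cr1, which encodes the fractalkine receptor, fell from 39.9 ± 5.13 to 2.69 ± 0.527 FPKM, and Il1b, which encodes the cytokine interleukin-1β, from 16.6 ± 7.1 to 0.584 ± 0.404. Fabp3 and Fabp4, which encode fatty acid binding proteins, rose from 7.21 ± 0.172 to 47.9 ± 0.981 and from 6.83 ± 0.823 to 35.5 ± 0.902 FPKM. Of the 12722 genes tested, 1919 rose and 1962 fell at an adjusted p under 0.05 (limma), and 112 of those that rose and 306 of those that fell changed at least 2-fold. The count was 1897 without the PBS replicate 1, 2135 without the PBS replicate 2, 2095 without the 5 µM replicate 1 and 1989 without the 5 µM replicate 2, fits that leave 1 sample in an arm.

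The other named genes with the largest rise at 5 µM were H2-M2, Cst7, Anpep, C77080, Trav13-4-dv7 and Mgll. H2-M2, a nonclassical class I histocompatibility gene, had a log2 change of 2.77 ± 0.10 (limma adjusted p = 0.000148). Cst7, which encodes cystatin F, an inhibitor of cysteine proteases, rose from 2.79 ± 0.206 to 20.5 ± 0.30 FPKM, and Anpep, which encodes aminopeptidase N (CD13), from 36.4 ± 0.585 to 186 ± 7.99. Mgll, which encodes monoacylglycerol lipase, rose from 1.31 ± 0.119 to 9.7 ± 0.255 FPKM, and C77080 from 3.1 ± 0.406 to 19.4 ± 0.364. Trav13-4-dv7, a T cell receptor gene segment, rose from 0.806 ± 0.362 to 7.8 ± 0.824 FPKM. It and H2-M2 belong to multigene families whose fragments an aligner can share between members, so these values are uncertain. F13a1, which encodes the A subunit of coagulation factor XIII, fell by 2.67 on the log2 scale, Cemip, which takes part in hyaluronan breakdown, by 2.63 and Marcksl1 by 2.58. Cnn1 and Actg2, contractile genes of smooth muscle, fell from 12.6 ± 1.26 to 1.4 ± 0.213 and from 44.3 ± 2.16 to 7.54 ± 1.3 FPKM. Gzme, one of several closely similar granzyme genes, fell from 29.4 ± 0.49 to 4.49 ± 2.01 FPKM. On GRCm38 the leading genes were annotated as follows: Cx3cr1 at chromosome 9, 119901616 to 120069879, Il1b at chromosome 2, 129364570 to 129371139, F13a1 at chromosome 13, 36867178 to 37050244, Fabp3 at chromosome 4, 130308595 to 130315463, Fabp4 at chromosome 3, 10204088 to 10208576 and Cst7 at chromosome 2, 150570415 to 150578944.

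Cell cycle genes fell together at 5 µM. Of the 41 cell cycle genes tested, 36 fell and 2 rose (37 and 2 adjusted over the list alone). The cell cycle median at 5 µM was -0.92 (camera adjusted p = 1.21e-17, and adjusted p = 0.41 with an estimated correlation), or -1.38 with voom on recovered fragments. Top2a, which encodes DNA topoisomerase II alpha, fell from 6.79 ± 0.362 to 2.04 ± 0.0791 FPKM and Ccna2, which encodes cyclin A2, from 3.97 ± 0.000636 to 1.22 ± 0.14. Of the 22 p53 targets, 12 rose and 3 fell (13 and 3 adjusted over the list alone). The p53 target median at 5 µM was 0.29 (camera adjusted p = 0.00552, and adjusted p = 0.41 with an estimated correlation). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 76 ± 2.72 to 124 ± 0.442 FPKM and Gadd45a from 6.65 ± 1.03 to 21.5 ± 0.416. Sesn1 fell from 27.5 ± 1.32 to 13.7 ± 0.257. Of the 29 immediate early and NFAT target genes, 14 fell and 4 rose (16 and 7 adjusted over the list alone). The immediate early median at 5 µM was -0.40 (camera adjusted p = 0.024, and adjusted p = 0.462 with an estimated correlation). Fos fell from 38 ± 0.0821 to 12.7 ± 2.07 FPKM and Dusp6, which encodes a phosphatase of ERK, from 42.8 ± 3.96 to 15.5 ± 2.55. With a filter of 5 FPKM the immediate early call was lost (adjusted p = 0.0583, range over the alternatives 0.0029 to 0.0583) and the median was -0.24. The median was -0.25 with no filter and -0.26 without the 5 µM replicate 2.

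Lysosomal genes rose at 5 µM. Of the 48 lysosomal genes, 36 rose and 4 fell (36 and 6 adjusted over the list alone). The lysosome median at 5 µM was 0.37 (camera adjusted p = 3.58e-08, and adjusted p = 0.418 with an estimated correlation). Atp6v1c1, which encodes a subunit of the proton pump that acidifies lysosomes, rose from 27.7 ± 0.999 to 50.7 ± 0.436 FPKM, and Mcoln1, which encodes a lysosomal cation channel, from 10.0 ± 0.27 to 17.7 ± 0.273. The glycoprotein gene Gpnmb rose from 1037 ± 46.4 to 2329 ± 42.9 FPKM. Of the 13 class II presentation genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone). The class II median at 5 µM was 0.35 (camera adjusted p = 0.00025, and adjusted p = 0.41 with an estimated correlation). With a filter of 5 FPKM, a pseudocount of 0.1 FPKM or voom the class II median was 0.54. H2-Aa and H2-Ab1, which encode class II chains, rose from 22.6 ± 0.21 to 72.6 ± 2.87 and from 42.7 ± 0.917 to 119.8 ± 7.2 FPKM. Of the 20 class I presentation genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone). The class I median at 5 µM was 0.25 (camera adjusted p = 0.000111, and adjusted p = 0.418 with an estimated correlation). H2-Q7 rose from 22 ± 0.337 to 59.6 ± 4.09 FPKM and H2-T23 from 249.9 ± 9.12 to 355 ± 4.53, with the same caution about fragments shared between related genes.

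Genes of the amino acid and ER stress response rose at 5 µM. Of the 40 genes of this list, 23 rose and 3 fell (25 and 4 adjusted over the list alone). The stress response median at 5 µM was 0.26 (camera adjusted p = 0.000111, and adjusted p = 0.418 with an estimated correlation). Ddit3, which encodes the transcription factor CHOP, rose from 17.4 ± 0.994 to 54.9 ± 0.995 FPKM and Atf4 from 50.8 ± 0.227 to 80.1 ± 1.86. Of the 25 NRF2 target genes, 10 rose and 2 fell (12 and 2 adjusted over the list alone). The NRF2 target median at 5 µM was 0.21 (camera adjusted p = 0.0016, and adjusted p = 0.52 with an estimated correlation). Gstm1, which encodes a glutathione S-transferase, rose from 64 ± 8.28 to 165 ± 10.8 FPKM. Of the 47 nuclear genes of the respiratory chain, 11 rose and 1 fell (10 and 1 adjusted over the list alone). The respiratory chain median at 5 µM was 0.10 (camera adjusted p = 0.0144, and adjusted p = 0.66 with an estimated correlation). Ndufs7, which encodes a complex I subunit, rose from 41.2 ± 0.191 to 54.1 ± 0.86 FPKM. The respiratory chain call was lost with fry (adjusted p = 0.128) and without the 5 µM replicate 1 (adjusted p = 0.0713, range over the alternatives 7.83e-05 to 0.128). Of the 13 genes encoded in the mitochondrial genome, 6 fell and 0 rose (6 and 0 adjusted over the list alone). The mitochondrial median at 5 µM was -0.52 (camera adjusted p = 0.00276, and adjusted p = 0.41 with an estimated correlation). All entries with a symbol that starts with mt-, in this list or not, held 0.885% and 0.947% of fragments in the PBS samples and 0.565% and 0.674% in the 5 µM samples.

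Markers of stromal cells and fibroblasts were lower at 5 µM. Of the 19 stromal and fibroblast markers, 12 fell and 0 rose (15 and 0 adjusted over the list alone). The stromal median at 5 µM was -1.22 (camera adjusted p = 1.6e-07, and adjusted p = 0.41 with an estimated correlation). Acta2, which encodes smooth muscle actin, fell from 664 ± 11.2 to 139 ± 14.2 FPKM and the collagen gene Col1a1 from 806 ± 35.5 to 263 ± 36.7. Of the 30 matrix and adhesion genes in the same samples, 19 fell and 2 rose (19 and 4 adjusted over the list alone). The matrix median at 5 µM was -0.48 (camera adjusted p = 8.33e-06, and adjusted p = 0.418 with an estimated correlation). Thbs1, which encodes thrombospondin 1, fell from 1019 ± 89 to 207 ± 10.1 FPKM and Mmp9, which encodes a gelatinase, from 116 ± 3.92 to 35.5 ± 1.16. Of the 9 neutrophil markers, 7 fell and 0 rose (8 and 1 adjusted over the list alone). The neutrophil median at 5 µM was -1.22 (camera adjusted p = 0.000111, and adjusted p = 0.41 with an estimated correlation), or -0.38 with no expression filter. S100a9 fell from 47.1 ± 2.55 to 15.5 ± 0.697 FPKM. Of the 30 macrophage identity genes, 15 fell and 9 rose (15 and 9 adjusted over the list alone). The macrophage identity median at 5 µM was -0.24 (camera adjusted p = 0.0392, and adjusted p = 0.507 with an estimated correlation). The complement gene C1qa fell from 1094 ± 4.08 to 469.7 ± 11.6 FPKM and Cd14, which encodes a coreceptor for lipopolysaccharide, from 385 ± 5.45 to 79.6 ± 12.2. The macrophage identity call was lost with median-of-ratios scaling (adjusted p = 0.0561), with a filter of 5 FPKM (adjusted p = 0.0617), and without either or both of the 10 µM samples (adjusted p = 0.0584 each, range over the alternatives 0.00636 to 0.0617).

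Chemokine and activation genes fell at 5 µM, in the samples in which stromal and neutrophil markers and mitochondrial transcripts were lower. Of the 22 chemokine and chemokine receptor genes, 10 fell and 3 rose (10 and 5 adjusted over the list alone). The chemokine median at 5 µM was -0.52 (camera adjusted p = 0.0172, and adjusted p = 0.418 with an estimated correlation). Ccl9 fell from 108 ± 9.11 to 41.6 ± 3.51 FPKM, and Ccrl2, an atypical chemokine receptor gene, rose from 7.31 ± 0.0781 to 21 ± 0.0907. Of the 24 classical activation genes, 13 fell and 3 rose (13 and 4 adjusted over the list alone). The classical activation median at 5 µM was -0.34 (camera adjusted p = 0.00276, and adjusted p = 0.497 with an estimated correlation). Of the 18 alternative activation genes, 11 fell and 3 rose (12 and 5 adjusted over the list alone). The alternative activation median at 5 µM was -0.55 (camera adjusted p = 0.0174, and adjusted p = 0.41 with an estimated correlation). Marco, which encodes a scavenger receptor, fell from 210.1 ± 10.4 to 64.6 ± 1.53 FPKM and Arg1, which encodes arginase 1, from 15.2 ± 1.41 to 2.81 ± 1.11. Without the PBS replicate 1 the chemokine median was -0.19. With no expression filter the medians were -0.34 for chemokines, -0.19 for classical activation and -0.17 for alternative activation.

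**Figure D1:**
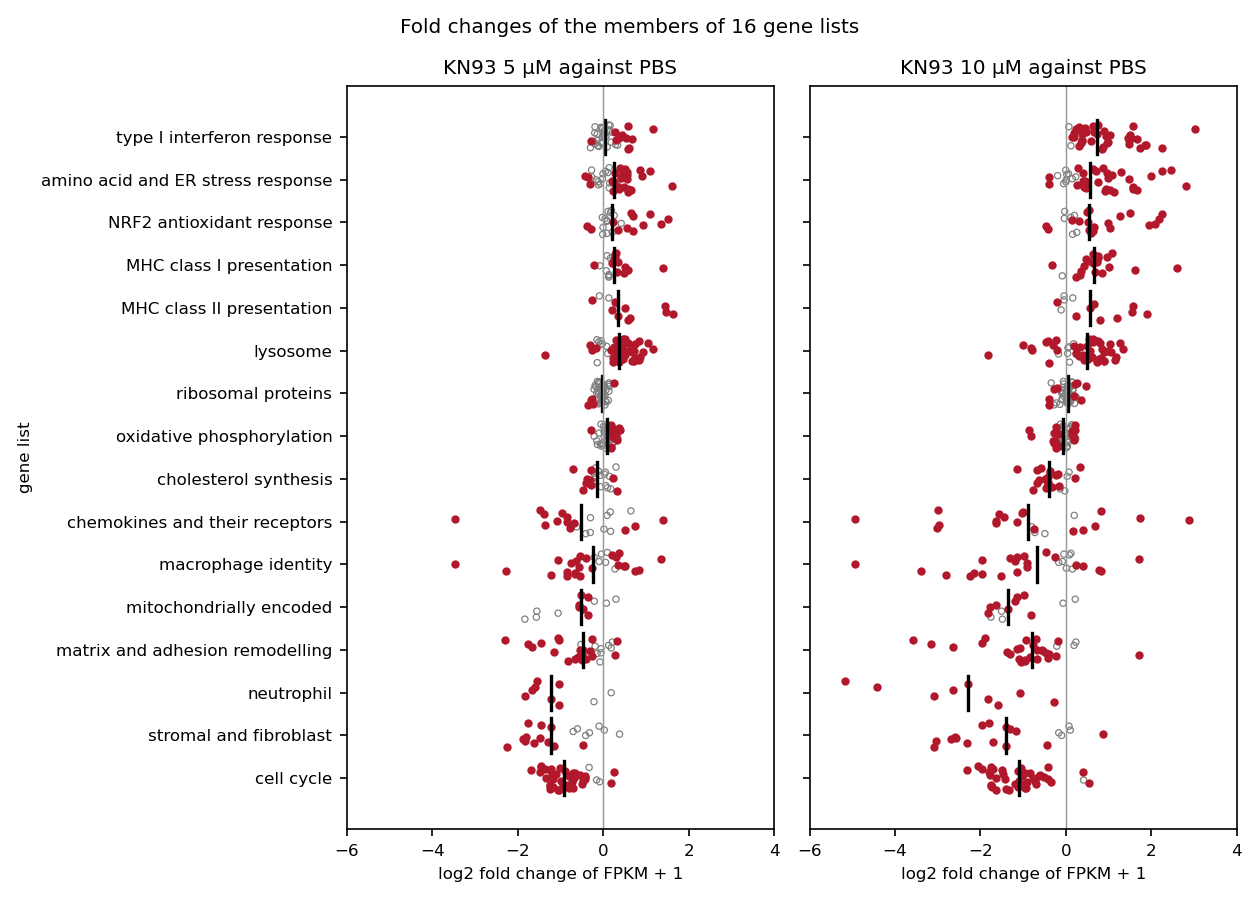
Each point is 1 tested gene of a list, at its log2 fold change of FPKM + 1 against PBS (horizontal axis) for 5 µM (left) and 10 µM (right). Filled red points passed an adjusted p under 0.05, open grey points did not, and black bars are list medians, which for the interferon list were 0.04 at 5 µM and 0.74 at 10 µM.

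The second comparison asked which transcripts differed between 10 µM KN93 and PBS. Lists of cell cycle, matrix, phagocytic and macrophage identity genes and of neutrophil and stromal markers were lower. Lists of interferon, antigen presentation, stress response and lysosomal genes were higher. None of them passed with an estimated correlation (smallest camera adjusted p = 0.314). Marco fell from 210.1 ± 10.4 to 3.36 ± 0.108 FPKM, the largest fall of a named gene on the log2(FPKM + 1) scale (log2 change -5.59 ± 0.05, limma adjusted p = 1.75e-06). Fabp3 rose from 7.21 ± 0.172 to 102 ± 1.47 FPKM, the largest rise on that scale (3.65 ± 0.04, limma adjusted p = 3.39e-06). Of the 12722 genes, 3631 rose and 2796 fell (limma, adjusted p under 0.05), 50.5% of those tested, and 394 and 604 of them changed at least 2-fold. That made 56.5% of the calls rises. With median-of-ratios scaling 2955 rose and 3219 fell, 47.9% rises, so which direction held more genes depended on the scaling.

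The other named genes with the largest rise at 10 µM were Cdkn1c, Orm1, Fabp4, Mgll, Sh2d6, Cox6a2 and Vwf. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, rose from 1.35 ± 0.541 to 25.3 ± 5.72 FPKM, and Vwf, which encodes von Willebrand factor, from 0.725 ± 0.0803 to 14.2 ± 0.539. Cox6a2, which encodes a cytochrome c oxidase subunit best known from muscle, rose from 1.3 ± 0.216 to 19.9 ± 0.472 FPKM, and Sh2d6 from 0.26 ± 0.00523 to 10.6 ± 0.44. Orm1, which encodes an acute phase protein, rose from 0.28 ± 0.0103 to 13.6 ± 4.18 FPKM, and it shares much sequence with its paralogs. Besides Marco, the largest falls were those of S100a9, Cx3cr1, F13a1, Ngp, Saa3, Chil3 and Il1b. S100a9 fell by 5.17, Cx3cr1 by 4.92, F13a1 by 4.59, the neutrophil granule gene Ngp by 4.43 and Il1b by 3.88 on the log2 scale. Saa3, a serum amyloid gene with close relatives, fell from 537 ± 129 to 31 ± 0.0452 FPKM, and Chil3, also known as Ym1, from 15.8 ± 0.113 to 0.125 ± 0.146. For genes near 0 FPKM in a group the size of the change depended on the pseudocount. With 0.1 FPKM it was -6.05 for Il1b, -6.32 for Chil3 and 4.89 for Sh2d6, and with voom on recovered fragments it was -6.74 for Ngp and 5.48 for Orm1. These sizes rest on few recovered fragments: 8 and 6 of Il1b, 9 and 1 of Chil3, 4 and 12 of Ngp and 6 and 3 of S100a9 in the 10 µM samples, and 6 and 6 of Orm1 and 12 and 13 of Sh2d6 in the PBS samples. On GRCm38 the leading genes of this comparison were annotated as follows: Marco at chromosome 1, 120474538 to 120505024, S100a9 at chromosome 3, 90692632 to 90695721, Cdkn1c at chromosome 7, 143458339 to 143461050, Mgll at chromosome 6, 88724412 to 88828360, Vwf at chromosome 6, 125546774 to 125686679 and Chil3 at chromosome 3, 106147554 to 106167564.

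**Figure D2:**
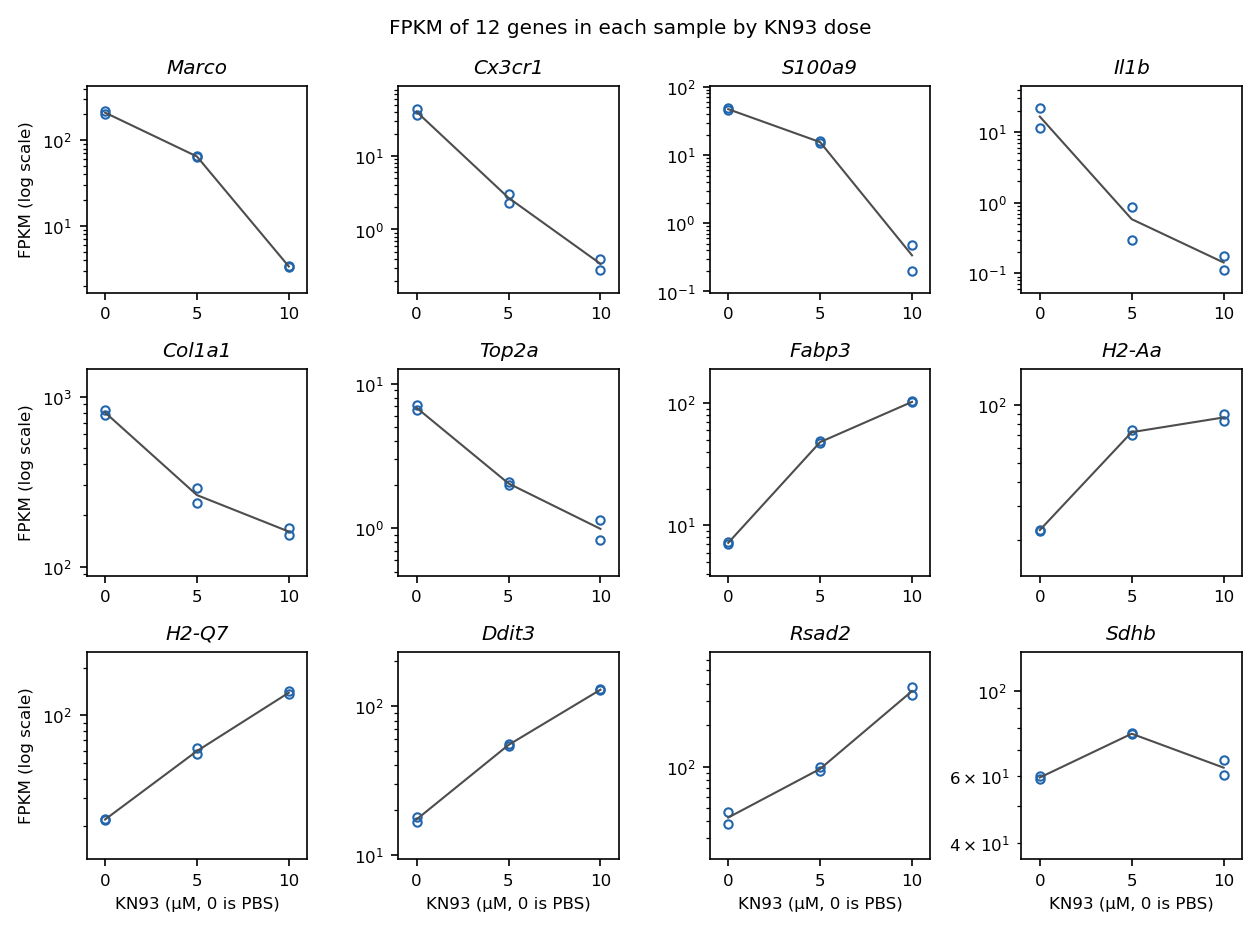
FPKM of 12 genes on a log axis (vertical) against KN93 dose in µM (horizontal), where open circles are the 2 samples of each group and lines join the group means. Marco went from 210.1 FPKM with PBS to 64.6 and 3.36, and Rsad2 from 42.5 to 96.1 and 354.

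Interferon-stimulated genes rose at 10 µM. Of the 40 genes of the type I interferon response, 38 rose and 0 fell (38 and 0 adjusted over the list alone). The interferon median at 10 µM was 0.74 (camera adjusted p = 3.24e-10, and adjusted p = 0.477 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, rose from 42.5 ± 6.32 to 354 ± 32.5 FPKM, Usp18 from 55.8 ± 5.18 to 169 ± 7.48 and Ifit1 from 61 ± 6.81 to 173 ± 6.98. At 5 µM 10 rose and 1 fell (10 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.129, median 0.04). It passed at 5 µM without the PBS replicate 1 (adjusted p = 0.000583, median 0.165) and with no expression filter (adjusted p = 0.0293), and its median was -0.014 without the PBS replicate 2 (adjusted p = 0.981, range over the alternatives 0.000583 to 0.981). Of the 20 class I presentation genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone). The class I median at 10 µM was 0.66 (camera adjusted p = 5.01e-06, and adjusted p = 0.323 with an estimated correlation). H2-Q7 rose to 139 ± 4.07 FPKM, and Tapbpl, which encodes a tapasin-related chaperone, from 20.1 ± 0.0257 to 43.8 ± 0.696. Of the 13 class II genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone). The class II median at 10 µM was 0.57 (camera adjusted p = 0.0171, and adjusted p = 0.477 with an estimated correlation), or 0.20 with no expression filter. H2-Aa rose to 86.5 ± 4.45 FPKM.

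Stress response genes rose at 10 µM as well. Of the 40 amino acid and ER stress genes, 28 rose and 2 fell (29 and 2 adjusted over the list alone). The stress response median at 10 µM was 0.57 (camera adjusted p = 2.96e-07, and adjusted p = 0.314 with an estimated correlation). Ddit3 rose to 129 ± 0.635 FPKM and Atf4 to 164 ± 5.34. Trib3, which encodes a pseudokinase induced by ATF4 and CHOP, rose from 8.03 ± 0.00785 to 48.4 ± 0.499 FPKM. Of the 25 NRF2 targets, 17 rose and 2 fell (18 and 2 adjusted over the list alone). The NRF2 target median at 10 µM was 0.54 (camera adjusted p = 0.00039, and adjusted p = 0.524 with an estimated correlation). Srxn1, which encodes sulfiredoxin, rose from 25.5 ± 1.29 to 73.5 ± 1.83 FPKM and Slc7a11, which encodes the cystine transporter, from 1.33 ± 0.323 to 10.0 ± 1.08. Of the 22 p53 targets, 15 rose and 2 fell (15 and 2 adjusted over the list alone). The p53 target median at 10 µM was 0.39 (camera adjusted p = 0.000865, and adjusted p = 0.314 with an estimated correlation), or 0.68 with a filter of 5 FPKM. Mdm2 rose from 20.2 ± 0.839 to 43 ± 1.36 FPKM. Of the 48 lysosomal genes, 31 rose and 10 fell (32 and 11 adjusted over the list alone). The lysosome median at 10 µM was 0.49 (camera adjusted p = 0.000747, and adjusted p = 0.55 with an estimated correlation). The acid alpha-glucosidase gene Gaa rose from 57.1 ± 1.57 to 119 ± 3.9. Of the 41 cell cycle genes, 38 fell and 2 rose (38 and 2 adjusted over the list alone). The cell cycle median at 10 µM was -1.11 (camera adjusted p = 2.54e-15, and adjusted p = 0.314 with an estimated correlation), or -1.72 with a pseudocount of 0.1 FPKM and -1.76 with voom. Top2a fell to 0.992 ± 0.22 FPKM, and Mcm5, which encodes a subunit of the replicative helicase, from 14 ± 1.59 to 3.36 ± 0.381.

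Macrophage identity genes were lower at 10 µM. Of the 30 genes of this list, 17 fell and 5 rose (17 and 5 adjusted over the list alone). The macrophage identity median at 10 µM was -0.69 (camera adjusted p = 0.000135, and adjusted p = 0.32 with an estimated correlation). C1qa fell to 155 ± 10.1 FPKM and Aif1 from 106 ± 7.85 to 21.7 ± 0.583. Of the 29 phagocytic and scavenger receptor genes, 18 fell and 3 rose (18 and 3 adjusted over the list alone). The phagocytic receptor median at 10 µM was -0.36 (camera adjusted p = 6.11e-06, and adjusted p = 0.314 with an estimated correlation). At 5 µM that list had not passed (camera adjusted p = 0.0623), though it did with no filter (0.0286), voom (0.0409) or fry (0.00472) and without the PBS replicate 2 (0.0339) or the 5 µM replicate 2 (0.0436, range over the alternatives 0.00472 to 0.1). Itgam, which encodes the integrin CD11b, fell from 52.6 ± 3.0 to 12.7 ± 0.321 FPKM and Stab1 from 229.5 ± 4.89 to 80.1 ± 3.27. Of the 22 chemokine and receptor genes, 12 fell and 6 rose (13 and 6 adjusted over the list alone). The chemokine median at 10 µM was -0.90 (camera adjusted p = 0.00163, and adjusted p = 0.314 with an estimated correlation). Ccl6 fell from 256 ± 6.26 to 30.6 ± 2.29 FPKM, and Ccrl2 rose from 7.31 ± 0.0781 to 60.0 ± 4.23. Of the 18 alternative activation genes, 11 fell and 5 rose (12 and 5 adjusted over the list alone). The alternative activation median at 10 µM was -0.70 (camera adjusted p = 0.00783, and adjusted p = 0.314 with an estimated correlation), or -0.26 with no expression filter. Mrc1, which encodes the mannose receptor, fell from 74.1 ± 3.36 to 15.2 ± 2.44 FPKM. Of the 24 classical activation genes, 12 fell and 7 rose (13 and 8 adjusted over the list alone). The classical activation median at 10 µM was -0.43 (camera adjusted p = 0.0424, and adjusted p = 0.594 with an estimated correlation), or -0.13 with no expression filter. Clec4e rose from 11.8 ± 1.45 to 66 ± 0.144 FPKM and Cd86, which encodes a costimulatory molecule, from 8.08 ± 0.796 to 27 ± 0.83. The classical activation call was lost with a filter of 5 FPKM (adjusted p = 0.247, median -0.11), with median-of-ratios scaling (0.0835) and with voom (0.0655). It was also lost without the PBS replicate 1 (adjusted p = 0.0816) or the 10 µM replicate 2 (adjusted p = 0.0815, range over the alternatives 0.0029 to 0.247).

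Markers of other cell types moved in the same 10 µM samples. Of the 9 neutrophil markers, 9 fell and 0 rose (9 and 0 adjusted over the list alone). The neutrophil median at 10 µM was -2.28 (camera adjusted p = 6.19e-07, and adjusted p = 0.314 with an estimated correlation), or -0.57 with no expression filter. Of the 19 stromal and fibroblast markers, 14 fell and 1 rose (14 and 1 adjusted over the list alone). The stromal median at 10 µM was -1.41 (camera adjusted p = 2.83e-06, and adjusted p = 0.314 with an estimated correlation). Acta2 fell to 76.9 ± 3.4 and Col1a1 to 161 ± 10.0 FPKM. The marker that rose was Kitl, which encodes stem cell factor, from 0.619 ± 0.0226 to 1.98 ± 0.666 FPKM, a gene chosen after its values were seen. Of the 30 matrix and adhesion genes, 26 fell and 1 rose (26 and 2 adjusted over the list alone). The matrix median at 10 µM was -0.79 (camera adjusted p = 4.39e-09, and adjusted p = 0.314 with an estimated correlation). Thbs1 fell to 85.6 ± 20.6 FPKM, and Itgb3, which encodes the integrin beta 3 chain, rose from 1.55 ± 0.0957 to 7.41 ± 0.0542. Fewer than 5 genes could be tested in 4 other marker lists, which had no list test. Of 3 lymphocyte genes, Cd79b, Cd4 and Ebf1 fell at 10 µM, with log2 changes of -1.83, -0.70 and -0.60. Of 2 mast cell and basophil genes, Mcpt8 and Siglecf fell (-1.20 and -0.42). Of 4 erythroid and megakaryocyte genes, Ppbp, Pf4 and Tfrc fell (-3.12, -3.00 and -0.34) and Vwf rose (3.14). Of 4 haematopoietic progenitor genes, Sox4, Cd93 and Myc fell (-0.80, -0.54 and -0.46), and Ly6a was 155 ± 0.269 FPKM with PBS and 159 ± 21.5 at 10 µM (limma adjusted p = 0.827). Without the PBS replicate 2 or the 10 µM replicate 2 the calls of Ebf1 (adjusted p = 0.0689 and 0.0581, range over the alternatives 0.000831 to 0.0689) and Siglecf (0.0964 and 0.0664, range over the alternatives 0.00487 to 0.0964) were lost. That of Myc was lost without either of these (0.0693 and 0.116) or the PBS replicate 1 (0.106), and with no filter (0.0799, range over the alternatives 0.00787 to 0.116). On the log2 scale with a pseudocount of 0.1 FPKM, which shrinks low genes less, Ebf1 fell by 1.31, Siglecf by 0.88 and Ppbp by 5.58.

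Genes of the mitochondrial genome fell at 10 µM. Of the 13 tested, 8 fell and 0 rose (8 and 0 adjusted over the list alone). The mitochondrial median at 10 µM was -1.35 (camera adjusted p = 0.000113, and adjusted p = 0.314 with an estimated correlation). All entries with a symbol that starts with mt- held 0.464% and 0.378% of fragments in the 10 µM samples. mt-Nd1, which encodes a subunit of complex I, fell from 523 ± 27.4 to 152 ± 7.26 FPKM. Of the 47 nuclear genes of the respiratory chain 13 fell and 6 rose (11 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.116, median -0.06). It passed with median-of-ratios scaling (adjusted p = 0.0471, median -0.12) and without the 10 µM replicate 2 (adjusted p = 0.00838, median -0.10, range over the alternatives 0.00838 to 0.668). Its median was 0 without the 10 µM replicate 1 and -0.03 without the PBS replicate 2. Of the 24 cholesterol synthesis genes, 18 fell and 2 rose (18 and 2 adjusted over the list alone). The cholesterol synthesis median at 10 µM was -0.39 (camera adjusted p = 5.86e-05, and adjusted p = 0.323 with an estimated correlation). At 5 µM that list had not passed (camera adjusted p = 0.11). Srebf2, which encodes the transcription factor that drives these genes, fell from 31.7 ± 0.574 to 19.6 ± 0.65 FPKM.

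The other 9 lists did not pass at 10 µM. Of 22 LXR target and lipid efflux genes 9 fell and 7 rose (10 and 8 adjusted over the list alone), with a camera adjusted p of 0.364, and Abca1, which encodes a cholesterol exporter, fell from 72.4 ± 4.26 to 10.3 ± 0.732 FPKM. Among 33 autophagy genes 18 rose and 7 fell (18 and 8 adjusted over the list alone), with a camera adjusted p of 0.0881. Sqstm1, which encodes an autophagy receptor, rose from 139 ± 7.27 to 464 ± 8.95 FPKM. For 17 inflammasome genes the counts were 9 lower and 6 higher (9 and 6 adjusted over the list alone, camera adjusted p = 0.105). Nlrp3 fell from 24.9 ± 0.000212 to 7.63 ± 0.209 FPKM. Among 29 immediate early and NFAT targets 16 fell and 10 rose (16 and 10 adjusted over the list alone), with a camera adjusted p of 0.0881, and Fos fell to 7.45 ± 0.535 FPKM. Among 31 glycolysis and hypoxia genes 12 rose and 4 fell (12 and 4 adjusted over the list alone), with a camera adjusted p of 0.286, and Hif1a fell from 52.5 ± 1.5 to 23.6 ± 1.14 FPKM. Among 14 osteoclast genes 8 rose and 6 fell (8 and 6 adjusted over the list alone), with a camera adjusted p of 0.608, and Clcn7, which encodes a lysosomal chloride transporter, rose from 58.9 ± 0.572 to 151 ± 2.78 FPKM. Of 50 ribosomal protein genes 5 rose and 4 fell (3 and 2 adjusted over the list alone), with a camera adjusted p of 0.906. Of 17 fatty acid synthesis genes 5 rose and 4 fell (5 and 4 adjusted over the list alone), with a camera adjusted p of 0.942. Of 7 dendritic cell markers 3 rose and 2 fell (3 and 2 adjusted over the list alone), with a camera adjusted p of 0.962. With no expression filter the autophagy, immediate early and glycolysis lists passed at 10 µM (adjusted p = 0.00786, 0.0181 and 0.0337), as they did with fry (0.00163, 0.0099 and 0.0229). Over the alternatives the adjusted p ran from 0.00163 to 0.107, from 0.0099 to 0.189 and from 0.0229 to 0.34. Fry also called the LXR target, inflammasome, osteoclast and dendritic cell lists (adjusted p = 0.0472, 0.00133, 0.000628 and 0.00413), the lowest of the alternatives, which reached 0.511, 0.16, 0.809 and 0.982. Median, mean and test did not share a sign for the ribosomal and dendritic cell lists at 10 µM and for the dendritic cell list at 5 µM, and none of these passed. The glycolysis list at 5 µM had a median of 0 and a mean of 0.07 (camera adjusted p = 0.582). No list passed with an estimated correlation in any comparison (camera). At an unadjusted p under 0.05, 1, 3 and 4 of the 29 lists did at 5 µM, at 10 µM and between the doses, and fry called 23, 26 and 19. The phagocytic receptor list at 10 µM had an estimated correlation of 0.003, below the preset 0.01. Its unadjusted camera p still went from 1.68e-06 to 0.0137. The interferon list had an estimated correlation of 0.691. A loss with an estimated correlation may therefore reflect the 3 residual degrees of freedom, correlated genes or both.

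The third comparison set the 2 doses against each other. Between 5 and 10 µM the lists of interferon, stress response, p53 target and class I presentation genes rose. Phagocytic receptor, macrophage identity, cholesterol synthesis and respiratory chain genes and neutrophil markers fell. With an estimated correlation 0 of them passed (smallest camera adjusted p = 0.2). Marco fell from 64.6 ± 1.53 to 3.36 ± 0.108 FPKM, and S100a9 from 15.5 ± 0.697 to 0.339 ± 0.193. Cxcl10, which encodes an interferon-induced chemokine, was 3.22 ± 1.33 FPKM with PBS and rose from 2.35 ± 0.322 at 5 µM to 12.8 ± 2.47 at 10 µM. Ptgir, which encodes the prostacyclin receptor, rose from 5.53 ± 0.144 to 24.2 ± 1.51 FPKM. The other genes with the largest rise were Cox6a2, Cdkn1c and Sh2d6, with log2 changes of 2.27 ± 0.08, 2.06 ± 0.20 and 1.99 ± 0.17. The other largest falls were those of Ngp, Saa3 and Chil3 (-2.83 ± 0.18, -2.63 ± 0.18 and -2.52 ± 0.10). With voom the change was -5.50 for S100a9, -6.02 for Chil3 and -5.02 for Ngp. Of 12722 genes, 1455 rose and 1081 fell (limma), so that 57.4% of the calls were rises. With median-of-ratios scaling 1097 rose and 1317 fell, 45.4% rises, so the balance of rises and falls depended on the scaling. Changes of at least 2-fold were found for 98 genes that rose and 94 that fell. The count was 1350 with no expression filter, which tests more genes. It was 1085 and 869 without the 5 µM replicates 1 and 2, and 1434 and 1449 without the 10 µM replicates 1 and 2, fits that leave 1 sample in an arm.

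Interferon-stimulated genes rose between the doses. Of the 40 genes of this list, 37 rose and 0 fell (39 and 0 adjusted over the list alone). The interferon median between the doses was 0.70 (camera adjusted p = 3.35e-17, and adjusted p = 0.32 with an estimated correlation). Gbp3, which encodes an interferon-induced GTPase, rose from 26.5 ± 0.411 to 79.7 ± 4.32 FPKM and Rsad2 from 96.1 ± 4.93 to 354 ± 32.5. Of the 20 class I presentation genes, 15 rose and 1 fell (17 and 1 adjusted over the list alone). The class I median between the doses was 0.38 (camera adjusted p = 2.59e-07, and adjusted p = 0.296 with an estimated correlation). H2-Q7 rose from 59.6 ± 4.09 to 139 ± 4.07 FPKM. Of the 40 amino acid and ER stress genes, 25 rose and 1 fell (29 and 1 adjusted over the list alone). The stress response median between the doses was 0.39 (camera adjusted p = 2.81e-10, and adjusted p = 0.252 with an estimated correlation). Trib3 rose from 15.5 ± 0.865 to 48.4 ± 0.499 FPKM. Of the 22 p53 targets, 10 rose and 1 fell (11 and 1 adjusted over the list alone). The p53 target median between the doses was 0.23 (camera adjusted p = 0.00121, and adjusted p = 0.252 with an estimated correlation). Of the 25 NRF2 targets, 10 rose and 0 fell (11 and 0 adjusted over the list alone). The NRF2 target median between the doses was 0.28 (camera adjusted p = 0.00303, and adjusted p = 0.554 with an estimated correlation). Plk2, a p53 target, rose from 21 ± 0.351 to 35.4 ± 1.63 FPKM and the NRF2 target Srxn1 from 40.8 ± 3.74 to 73.5 ± 1.83. The NRF2 call was lost with fry (adjusted p = 0.0555, range over the alternatives 0.000109 to 0.0555), and its median without the 5 µM replicate 2 was 0.18.

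Macrophage identity, phagocytic receptor, chemokine and alternative activation genes fell between the doses. Of the 30 macrophage identity genes, 14 fell and 2 rose (16 and 2 adjusted over the list alone). The macrophage identity median between the doses was -0.32 (camera adjusted p = 2.92e-10, and adjusted p = 0.252 with an estimated correlation). C1qc fell from 575 ± 4.91 to 205 ± 0.913 FPKM. Of the 29 phagocytic and scavenger receptor genes, 15 fell and 2 rose (20 and 2 adjusted over the list alone). The phagocytic receptor median between the doses was -0.43 (camera adjusted p = 7.38e-09, and adjusted p = 0.200 with an estimated correlation), or -0.25 with no expression filter. Stab1 fell from 149 ± 5.69 to 80.1 ± 3.27 FPKM. Of the 22 chemokine and receptor genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone). The chemokine median between the doses was -0.24 (camera adjusted p = 0.000174, and adjusted p = 0.252 with an estimated correlation). Ccl6 fell from 149.9 ± 6.85 to 30.6 ± 2.29 FPKM. The chemokine median was -0.49 without the 10 µM replicate 1 and -0.10 without the 10 µM replicate 2. It was -0.14 with no filter, -0.39 with a pseudocount of 0.1 FPKM and -0.52 with voom. Of the 18 alternative activation genes, 8 fell and 1 rose (8 and 3 adjusted over the list alone). The alternative activation median between the doses was -0.19 (camera adjusted p = 0.00361, and adjusted p = 0.252 with an estimated correlation). Without an expression filter it was -0.04, with a filter of 5 FPKM -0.31, and with a pseudocount of 0.1 FPKM or voom -0.32. Mrc1 fell from 36.8 ± 0.911 to 15.2 ± 2.44 FPKM.

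Respiratory chain, mitochondrial, cholesterol synthesis and LXR target genes fell between the doses. Of the 47 nuclear respiratory chain genes, 16 fell and 0 rose (22 and 0 adjusted over the list alone). The respiratory chain median between the doses was -0.16 (camera adjusted p = 5.4e-08, and adjusted p = 0.429 with an estimated correlation). The call was lost with fry (adjusted p = 0.0503, range over the alternatives 1.36e-12 to 0.0503). Ndufs8, which encodes a complex I subunit, fell from 47.7 ± 1.44 to 31.3 ± 1.62 FPKM and Ndufa4 from 33.2 ± 1.36 to 21.5 ± 1.79. Of the 13 mitochondrially encoded genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone). The mitochondrial median between the doses was -0.47 (camera adjusted p = 8.69e-05, and adjusted p = 0.252 with an estimated correlation), or -1.07 without the 5 µM replicate 1. Their share of fragments was 0.565% and 0.674% at 5 µM and 0.464% and 0.378% at 10 µM. Of the 24 cholesterol synthesis genes, 11 fell and 0 rose (16 and 0 adjusted over the list alone). The cholesterol synthesis median between the doses was -0.23 (camera adjusted p = 1.49e-07, and adjusted p = 0.28 with an estimated correlation). Dhcr7, which encodes the last enzyme of the pathway, fell from 8.27 ± 0.229 to 5.23 ± 0.107 FPKM. Of the 22 LXR target and lipid efflux genes, 9 fell and 3 rose (13 and 3 adjusted over the list alone). The LXR target median between the doses was -0.25 (camera adjusted p = 0.00281, and adjusted p = 0.429 with an estimated correlation). Abca1 fell from 32.9 ± 1.34 to 10.3 ± 0.732 FPKM, and Fabp4 rose from 35.5 ± 0.902 to 76.2 ± 7.69. Of the 17 fatty acid synthesis genes, 2 fell and 2 rose (3 and 2 adjusted over the list alone). The fatty acid synthesis median between the doses was -0.10 (camera adjusted p = 0.0337, and adjusted p = 0.466 with an estimated correlation). Fads1 and Acly fell and Acss2 and Mid1ip1 rose, with log2 changes of -0.37, -0.26, 0.56 and 0.26. The Acly call was lost with no filter (adjusted p = 0.077), with only the groups compared (0.0589), without either PBS sample (0.0598 each), without the 5 µM replicate 1 or 2 (0.115 and 0.127) and without the 10 µM replicate 2 (0.0712, range over the alternatives 0.0134 to 0.127). The Mid1ip1 call was lost with no filter (adjusted p = 0.0526), without the 5 µM replicate 1 or 2 (0.111 and 0.0636) and without the 10 µM replicate 1 or 2 (0.0832 and 0.0631, range over the alternatives 0.0146 to 0.111). The fatty acid call was lost with a filter of 5 FPKM (adjusted p = 0.118), with fry (0.168) and without the 10 µM replicate 2 (0.171) or the 5 µM replicate 1 (0.132, range over the alternatives 0.00576 to 0.171).

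Cell cycle genes and markers of other cell types also fell between the doses. Of the 41 cell cycle genes, 12 fell and 1 rose (17 and 1 adjusted over the list alone). The cell cycle median between the doses was -0.24 (camera adjusted p = 4.32e-08, and adjusted p = 0.296 with an estimated correlation), or -0.39 with a pseudocount of 0.1 FPKM and -0.42 with voom. Top2a fell from 2.04 ± 0.0791 to 0.992 ± 0.22 FPKM, a call lost without the 5 µM replicate 1 (adjusted p = 0.0593) or 2 (adjusted p = 0.0552, range over the alternatives 0.0012 to 0.0593). Of the 9 neutrophil markers, 7 fell and 0 rose (8 and 0 adjusted over the list alone). The neutrophil median between the doses was -1.25 (camera adjusted p = 4.32e-08, and adjusted p = 0.252 with an estimated correlation), or -0.08 with no expression filter. Ngp fell from 7.91 ± 2.22 to 0.241 ± 0.149 FPKM. Of the 19 stromal and fibroblast markers, 8 fell and 0 rose (8 and 0 adjusted over the list alone). The stromal median between the doses was -0.41 (camera adjusted p = 0.00303, and adjusted p = 0.429 with an estimated correlation), or -0.70 with a filter of 5 FPKM. The stromal call was lost with fry (adjusted p = 0.0718) and without the 10 µM replicate 2 (adjusted p = 0.0632, median -0.26, range over the alternatives 0.000105 to 0.0718). Of the 30 matrix and adhesion genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone). The matrix median between the doses was -0.27 (camera adjusted p = 2.48e-07, and adjusted p = 0.296 with an estimated correlation). Mmp9 fell from 35.5 ± 1.16 to 17.6 ± 1.03 FPKM. The lysosome list did not pass between the doses (camera adjusted p = 0.767). Of its genes 12 rose and 10 fell (16 and 13 adjusted over the list alone), and its median was 0.07 and its mean -0.01. The median was 0.04 without the 10 µM replicate 2 and 0.03 with median-of-ratios scaling. Neither the classical activation list nor the class II list passed (camera adjusted p = 0.497 for each).

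The 2 dose steps were also compared with each other, as the change from 5 to 10 µM minus the change from PBS to 5 µM (limma). The second step was higher than the first for 366 of 12722 genes and lower for 316. Without the 5 µM replicate 1 or 2 the counts were 0 and 0, and 1 and 1, though 2359 and 1985 genes had an unadjusted p under 0.05, against 3291 with all samples. They were 20 and 25 without the PBS replicate 1, 87 and 69 without the PBS replicate 2, 11 and 16 without the 10 µM replicate 1, and 134 and 105 without the 10 µM replicate 2. With no filter they were 11 and 34, and with voom 640 and 580. Of the 29 lists, 14 passed this test, 6 with the second step higher and 8 with it lower, and none passed with an estimated correlation (camera). Fry called 0 of them (smallest adjusted p = 0.055), and 13 at an unadjusted p under 0.05. The interferon list lay higher in the second step, with 11 members higher and 0 lower and a median difference of 0.55 (camera adjusted p = 1.49e-11, and adjusted p = 0.56 with an estimated correlation). The lysosome list lay lower, with 16 members lower and 1 higher and a median difference of -0.42 (camera adjusted p = 2.79e-13, and adjusted p = 0.56 with an estimated correlation). The cell cycle list lay higher, the fall being smaller in the second step, with 6 members higher and 0 lower and a median difference of 0.65 (camera adjusted p = 5.43e-13, and adjusted p = 0.56 with an estimated correlation). With fry the adjusted p was 0.087 for the interferon list and 0.055 for each of the lysosome and cell cycle lists, and the lowest over the alternatives was 7.25e-16, 2.06e-21 and 5.16e-19. No member of these 3 lists was called without the 5 µM replicate 1 or 2 or the 10 µM replicate 1, or with no filter. Without the PBS replicate 1 or 2 there were 1 and 9 interferon members and 0 of the others, and without the 10 µM replicate 2 there were 3 interferon, 5 lysosome and 1 cell cycle members. Both steps use the 5 µM samples with opposite signs, so chance values in those samples push the steps apart.

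Across genes, which are not independent replicates, the fold changes of the 2 doses against PBS had a Pearson correlation of 0.856. Simulated unchanged groups against the same PBS samples gave 0.504. The covariance was 0.208 against 0.00952 simulated, a difference of 0.199. Both doses raised 1675 genes and lowered 1720, where independent lists would share 548 and 431. At one dose up and at the other down were 31 genes, where independent lists give 982. Without the PBS replicate 1 or 2 both doses raised 808 and 923 genes and lowered 968 and 1032, and 6 and 11 genes went opposite ways. Without the 5 µM replicate 1 or 2 these counts were 841 and 867, 1114 and 1023, and 12 and 7. Opposite ways went 9 genes with no filter, and 19 with no intensity trend. With each dose set against a different PBS sample, a split chosen after seeing the data, the correlation was 0.737 and 0.753 in the 2 arrangements and the covariance 0.193 in each. Both doses then raised 837 and 789 genes, where independent lists would share 197 and 177, and lowered 986 and 954, where such lists would share 186 and 175. Each dose had 1 control sample in the split, so part of the excess seen with both PBS samples may come from the shared controls.

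**Figure D3:**
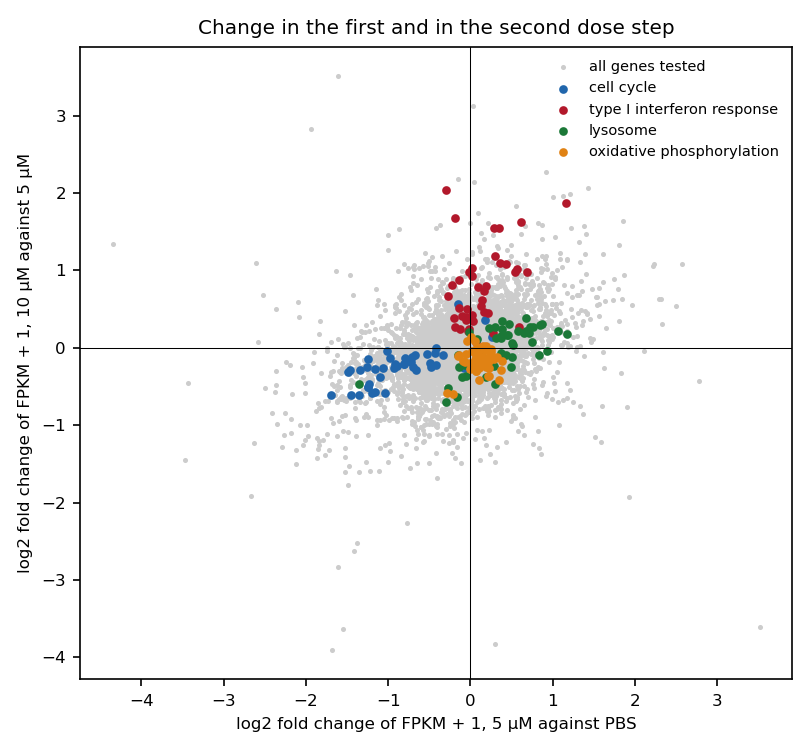
Each point is 1 of the 12722 tested genes, at its log2 fold change of FPKM + 1 from PBS to 5 µM (horizontal axis) and from 5 to 10 µM (vertical axis), with 4 gene lists in colour. Interferon genes lie near 0 in the first step and above 0 in the second (medians 0.04 and 0.70), cell cycle genes lie mostly to the left (median -0.92), and the 5 µM samples enter both axes with opposite signs.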

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

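In this part the tests of type I interferon transcription and of length, GC content and level for the fall of the respiratory chain were set before their results were seen, and the other 7 tests were chosen after. The groups held 2 samples, too few to test a single sample against its group.

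The list of nuclear respiratory chain genes drew attention because it rose from PBS to 5 µM and fell from 5 to 10 µM, with medians of 0.098 and -0.156, each step passing its own test (camera adjusted p = 0.0144 and 5.4e-08) in a pair of steps that share the 5 µM samples. Against the fall being an effect of exon length, GC content and expression level, its median of -0.156 lay below the central 95% (-0.049 to 0.116) of 10000 lists matched on these, whereas the median of 0.098 at 5 µM lay within theirs (-0.056 to 0.117, percentile 94.14), so those properties may account for the rise. Scaling also shifts the other genes, so camera cannot decide on it (largest adjusted p 6.28e-08 for the fall and 0.0228 for the rise). With an estimated correlation neither step passed (adjusted p = 0.429 for the fall and 0.66 for the rise), nor did the difference of the steps (0.56, and 0.0923 with fry). A dose-dependent effect of KN93 on these genes stays open for the fall, as do scaling and chance values of the shared 5 µM samples.

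The rise of interferon-stimulated genes between 5 and 10 µM was weighed because the list lay higher in the second step than in the first (median difference 0.55, camera adjusted p = 1.49e-11, and adjusted p = 0.56 with an estimated correlation and 0.087 with fry). A single 10 µM library as the source is argued against by the median rise, which was 0.634 without replicate 1 and 0.74 without replicate 2, with 25 and 30 of 40 members called. Scaling is argued against by the 34 members called under median-of-ratios scaling and the 35 under quantile normalization. Transcription of type I interferon genes stays undecided, because their recovered fragments were 2 and 11 in the 10 µM samples against 5 and 5 with PBS and 4 and 1 at 5 µM, and Ifnb1 gave both the 2 and the 11. A response of the cells to the higher dose, whether or not through secreted interferon, is a hypothesis that these samples leave open.

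The fall of stromal and fibroblast genes was weighed because a smaller share of stromal cells in the treated cultures could produce it. Uniform stromal cells would lose their transcripts by one common factor. The log2 ratios of FPKM at 10 µM against PBS were -2.33 for Col1a1, -1.71 for Col1a2, -3.80 for Col3a1 and -2.83 for Col5a1. Their range of 2.08 (standard error 0.65) argues against a smaller share of uniform cells as the whole cause. Against scaling, 14 of the 19 members were lower at 10 µM under each of the 2 scalings. Loss of a mix of stromal cells stays open, as do a smaller share with changed expression and lower expression in macrophages. Col3a1, with a mean of 1.29 FPKM at 10 µM, had the widest error (0.65), and without it the range was 1.12 (standard error 0.17).

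Among the named genes, 11 also passed in both steps with opposite signs. Their steps differed (limma adjusted p = 0.0046 to 0.0482), but that choice and chance values of the shared 5 µM samples favour this. The log2 changes from PBS to 5 µM and from 5 to 10 µM were 2.775 and -0.434 for H2-M2, a nonclassical class I gene. They were 0.374 and -0.292 for Sdhb, which encodes a subunit of respiratory complex II. The class II pathway genes Ifi30 and H2-DMa had 0.277 and -0.494, and 0.201 and -0.311. For Itgax, which encodes CD11c, the steps were 0.381 and -0.521, and for Gas6, a ligand of TAM receptors, 0.292 and -0.901. For Camk1, a kinase of the CaMK family, they were 0.299 and -0.329, and for the lysosomal enzyme gene Glb1 0.184 and -0.379. A fall followed by a rise was seen for Slc16a3, a lactate transporter gene (-0.276 and 0.204), for P4ha1 (-0.245 and 0.334) and for Junb, a gene of the AP-1 transcription factor (-0.437 and 0.377). Junb kept both calls under every alternative except a required log2 fold change of at least 1, which none of these 11 genes met in both steps. The first step was lost without any one of the PBS or 5 µM samples for Glb1 (adjusted p = 0.0954 to 0.145), H2-DMa (0.0959 to 0.165), Ifi30 (0.0724 to 0.0792), P4ha1 (0.0568 to 0.144) and Itgax (0.0776 to 0.165). It was lost without the PBS replicate 1 or either 5 µM sample for Camk1 (0.0584 to 0.085) and Gas6 (0.0521 to 0.0838), and without either PBS sample or the 5 µM replicate 2 for Slc16a3 (0.0532 to 0.0686). With no filter it was lost for H2-DMa (0.0683), P4ha1 (0.0743) and Itgax (0.111), and with no intensity trend for Glb1 (0.0542) and H2-DMa (0.0554). The second step was lost without any one of the 5 or 10 µM samples for H2-M2 (adjusted p = 0.0817 to 0.131), and without either 5 µM sample or the 10 µM replicate 1 for Itgax (0.0574 to 0.109), Camk1 (0.0639 to 0.0948) and Sdhb (0.0532 to 0.101). For H2-DMa it was lost without either 5 µM sample (0.0737 to 0.0774), and for P4ha1 without the 5 µM replicate 2 or the 10 µM replicate 1 (0.0645 to 0.0946). With no filter it was lost for H2-M2 (0.101), Itgax (0.077), Sdhb (0.054) and P4ha1 (0.0534). That of Slc16a3 was lost without any one of the 6 samples (0.0764 to 0.18), with no filter (0.0737), with no intensity trend (0.0572), with median-of-ratios scaling (0.0702), with quantile normalization (0.0591) and with only the 2 groups compared (0.0767). Over all alternatives the adjusted p of the steps with a loss ranged from 0.00356 to 0.18. In all, 188 of 12722 genes were called in opposite directions in the 2 steps, where independent lists give 387. This count was 88 with no filter, 50 and 77 without the PBS replicate 1 or 2, 57 and 34 without the 5 µM replicate 1 or 2, and 102 without the 10 µM replicate 1.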

How the results depend on the processing

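The voom fit, the split of the PBS samples and the alternatives for the steps and the shared calls were chosen after seeing the data. In the voom fit 4359, 6676 and 3165 genes were called at 5 µM, at 10 µM and between the doses. Under every alternative except those named here, the counts of genes and lists called in the 3 comparisons, of those whose steps differed and of genes called alike at both doses stayed within 1.5 times, and the correlation of the 2 doses ran from 0.808 to 0.879. With each dose against a PBS sample of its own it was 0.737 and 0.753, with fewer samples and no shared control by construction. Requiring a log2 fold change of at least 1 as well left 418, 998 and 192 genes, by construction. With no filter 1350 genes were called between the doses, among more genes tested. With an estimated correlation 0, 0 and 0 lists passed (camera), though 1, 3 and 4 did at an unadjusted p under 0.05 and fry called 23, 26 and 19. Leaving out 1 sample gave 1897 to 3856 genes at 5 µM, 4575 to 5977 at 10 µM and 869 to 1922 between the doses. Where it leaves 1 sample in an arm, that sample is assumed to vary like the other groups, and fewer samples is the cause by construction. Genes whose steps differed were 45 with no filter, 1220 with voom and 0 to 239 with 1 sample left out. Fry called 0 lists for the steps. Genes with opposite steps were 88 with no filter and 34 to 137 with 1 sample left out, and genes called alike at both doses 1776 to 3244. Of 569 results of named genes past the threshold, 114 were lost under at least 1 alternative, 67 under one other than leaving out a sample, and 0 changed direction. The list medians that changed sign all belonged to lists that had not passed, and the cause was not tested. At 5 µM these were -0.004 for CaMK with median-of-ratios scaling, -0.003 and -0.021 for glycolysis, whose median was 0, with a filter of 5 FPKM and with that scaling, and -0.014 for dendritic cells with no filter. At 10 µM they were -0.024 for ribosomal proteins with median-of-ratios scaling and -0.006 for osteoclasts with no filter. Between the doses they were 0.034 for classical activation and -0.249 for dendritic cells with a filter of 5 FPKM, and -0.007 for each of osteoclasts and dendritic cells with no filter. Leaving out 1 sample gave medians of -0.014 to 0.165 for interferon and -0.096 to 0.014 for ribosomal proteins at 5 µM. At 10 µM it gave -0.1 to 0.008 for CaMK, -0.018 to 0.171 for fatty acid synthesis and -0.047 to 0.11 for ribosomal proteins, and between the doses -0.05 to 0.004 for classical activation. At this depth the simulation, with genes of equal spread, recovered 40% of those with its smallest fold. It was not split by level, so limits from depth and sample number were not separated.

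With the replicate number as a block, 3409, 6023 and 2079 genes and 16, 17 and 18 lists were called in the 3 comparisons, and the steps of 354 genes differed. Of 658 results of named genes and lists, 23 were no longer past the threshold, 0 were newly past it and 0 changed direction. Of these, 2 were lists (macrophage identity at 5 µM and classical activation at 10 µM) and 21 were of genes, among them the first step of Glb1 and H2-DMa and the second of Slc16a3. The correlations of the deviations of same-numbered samples were -0.055, 0.014 and 0.037, so the numbers do not show a pairing.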

Other observations

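The gene families in this part were chosen after their values were seen. A change named here was called with an adjusted p under 0.05 (limma), and its direction was the same under median-of-ratios scaling and quantile normalization except where stated. Guanylate-binding proteins, interferon-induced GTPases of host defence, were mixed at 5 µM, with 2 of 9 higher and 2 lower (1 lower with quantile normalization). At 10 µM 8 of the 9 were higher than with PBS. Gbp11 rose from 0.54 ± 0.0957 FPKM with PBS to 2.61 ± 0.557 at 5 µM and 9.54 ± 1.67 at 10 µM, and Gbp2 was 41.2 ± 7.11, 52.1 ± 0.83 and 154 ± 9.48 FPKM. Of 7 Schlafen genes, growth regulators that respond to interferon, 4 rose and 1 fell at 5 µM and 6 rose at 10 µM. Slfn4 rose from 22.2 ± 3.72 to 46.8 ± 3.59 and 96 ± 18.8 FPKM, while Slfn9 was 10.7 ± 0.781, 6.12 ± 0.227 and 9.56 ± 0.795. Both metallothioneins tested, which bind zinc and copper, rose at both doses. Mt2 went from 20.1 ± 2.14 to 81.6 ± 11.7 and 119.9 ± 0.417 FPKM and Mt1 from 47.1 ± 6.07 to 81.9 ± 6.3 and 102 ± 9.54. Of 17 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 5 rose at 5 µM and 12 at 10 µM with 0 lower, though 1 was lower at 10 µM with median-of-ratios scaling. Sars rose from 21.9 ± 0.0134 to 32.4 ± 1.67 and 47.4 ± 0.163 FPKM and Aars from 23 ± 0.471 to 34.8 ± 0.613 and 51.1 ± 2.01.

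All 4 fatty acid binding proteins tested rose at both doses, and Fabp5 went from 203 ± 13 to 568 ± 14 and 616 ± 33.1 FPKM. The 3 paired immunoglobulin-like receptors of the Pilr family fell at both doses and again between them. Pilra went from 35.4 ± 7.46 to 11.9 ± 0.503 and 2.75 ± 0.156 FPKM, and Pilrb1 and Pilrb2 are close paralogs whose fragments an aligner can share. Both Tmem176 genes, which encode membrane proteins of myeloid cells, fell at both doses. Tmem176b went from 121 ± 9.35 to 39.4 ± 0.0754 and 19.9 ± 1.1 FPKM and Tmem176a from 32.5 ± 2.14 to 10.3 ± 0.233 and 6.35 ± 0.169. The 3 granzymes tested, Gzmc, Gzmd and Gzme, fell at both doses and share much sequence. Gzmc went from 5.37 ± 0.777 to 0.495 ± 0.0993 and 0.976 ± 0.321 FPKM, and 0 of the 3 were called between the doses.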
